A study of Drosophila melanogaster with 3 samples.

How the data were processed

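Binding of pb-GFP was measured by ChIP-seq with an antibody against GFP in 3 biological replicates of whole transgenic embryos aged 0 to 24 h, from chromatin sheared to 200 to 800 bp. All 3 libraries form 1 group. The authors deposited peak lists in narrowPeak format on dm6 and dm3. Per the deposited notes, each replicate list was called on that replicate's alignments and 1 control, and holds 30000 peaks and background regions. The combined list was called on the alignments of the 3 replicates together, and the thresholded list was made from it on the irreproducible discovery rate. On both builds the thresholded list holds exactly the strongest peaks of the combined list by signal value. The deposited lists give for each peak the authors' signal value, whose statistic and normalization are not given in the sources used here, so that it was used as ranks within a list, except for Pearson's r of its log2 between libraries and for the map of the Antennapedia complex, which shows it as deposited. They also give the deposited −log10 q of each peak, which has a ceiling reached by many peaks. The p column was not given. The aligner, the peak caller and their versions are not given in the sources used here. Signal tracks, reads and the control were not analysed here, and the read depth per library is unknown, so no interval for counting error of reads is given.

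The main lists were those on dm6, with the Ensembl release 115 gene annotation (FlyBase release 6.54) and the Release 6 genome sequence. Peaks were counted as shared when summits lay within 100 bp. Promoters were the 1000 bp to either side of a start site of a protein-coding gene, and the other classes were assigned in the order 5′ UTR, coding exon, 3′ UTR, intron, intergenic. Chance for recovery, overlap and annotation came from 1000 circular shifts of the peaks within each arm, as 2-sided permutation tests. The arm length was the extent of the peaks in the replicate lists, since no file of euchromatin boundaries was at hand, and arms were compared by 2-sided exact binomial tests. Gene lists were tested by counting members whose start site was nearest to a thresholded summit, against 1000 random peak sets that keep each peak's distance to its start site and its arm (2-sided permutation test). Motifs were counted on either strand within 100 bp of the summit and in windows centred 1000 bp to either side, with a 2-sided sign-flip permutation test over peaks (100000 resamples). The pb gene with 50 kb to either side was compared with 1000 random windows. Values of p were adjusted by the Benjamini-Hochberg method within annotation classes, arms, the 23 lists and the 11 motifs, with a threshold of 0.05. Replicate values are those of the 2740 highest ranked peaks of each library, with the SD over 3. Intervals for shares of peaks are exact (Clopper-Pearson) at 95%.

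The 23 lists were Hox genes, other Antennapedia complex regulators, Hox cofactors and other TALE homeobox genes, Polycomb and trithorax group, gap and head patterning, pair rule, segment polarity, appendage patterning, neuroblast and proneural regulators, neuronal identity regulators, glial regulators, mesoderm and muscle regulators, salivary gland and tracheal regulators, GATA factors and blood cell regulators, Notch pathway and targets, EGF receptor pathway, BMP and Wnt ligands and receptors, cell death inducers, axon guidance and cell adhesion, and 4 contrast lists (cytoplasmic ribosomal proteins, odorant and gustatory receptors, cytochrome P450 and proteasome subunits). The contrast lists were fixed as patterns of gene symbols, and the one for cytochrome P450 also took in the cyclophilin genes Cyp1 and Cyp40. The symbols h and Dl were read as hry and Delta. Genes were named by a fixed rule: the Hox genes, exd and hth; the genes nearest to the 15 strongest thresholded peaks found in all 3 replicate lists; up to 4 members with the strongest peaks of each list that passed; and the 5 genes with most peaks.

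Alternatives were the dm3 lists, the 1370 strongest peaks, other distances that count as shared, other list depths, promoter windows, motif windows and flanks, other random backgrounds, Fisher's exact test, other assignments of peaks to genes, and leaving out each replicate. The 1370 strongest peaks stood for a stricter threshold. The lists give no irreproducible discovery rate per peak, and all 2740 thresholded peaks have the same −log10 q, the largest of the list. For annotation, arms, gene lists, motifs and the pb locus, a replicate was left out by keeping the thresholded peaks among the top peaks of both other libraries. The library left out still contributed to the combined list, and the set is smaller, so a call lost this way does not by itself show dependence on that library. Leaving out a replicate for the promoter share, annotation, arms and motifs, unmasked bases as the arm length, classes among summits outside promoters, and the P450 list without the cyclophilin genes were added after the data were examined. The code was run on simulated data. A planted overlap of 60.6% was measured as 60.6%. For gene lists, 0 of 60 null lists had an unadjusted p under 0.05, and 19 of 20 lists with planted peaks were called. These lists were random genes, and their peaks came from the same random placement as the test. They do not show how the test behaves for neighbouring genes or for genes with long sequence nearest to them. A motif planted in 9.78% of centres was measured at 9.74 points above the flanks, and 0 of 2 motifs not planted were called. A promoter share of 44.7% was measured as 44.7%. The overlap and promoter shares were fixed by how the peaks were placed, so these 2 runs check only the counting. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.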

Results

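Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the binding of proboscipedia (pb) in whole embryos of Drosophila melanogaster. pb is a Hox gene of the Antennapedia complex that is needed for the adult mouthparts, and its product is a homeodomain transcription factor. The embryos were aged 0 to 24 h, were of both sexes, and came from a transgenic line in which pb carries green fluorescent protein (GFP) at its C terminus. An antibody against GFP recovered the fusion protein together with sheared chromatin of 200 to 800 bp. The 3 libraries were biological replicates of a single group, and the data hold no contrast between conditions. They answer where peaks were called and how far the libraries repeated each other. No library without the tagged protein and no control was analysed here. Recovery that depends on pb-GFP was therefore not told apart from recovery that does not, and pb-GFP peaks below are meant in that sense. Each library was represented by 30000 peaks and background regions ranked by the authors' signal value. At the largest −log10 q of its list stood 1199 peaks in replicate 1, 1587 in replicate 2 and 2523 in replicate 3. The list that the authors thresholded on the irreproducible discovery rate (IDR) held 2740 peaks on dm6, with no replicate error of its own because it combines the libraries. The tests, gene lists, motifs and rules for naming genes were fixed before the data were examined. Read depth is unknown, and the signal value was used to rank peaks within a list, except in Pearson's r of its log2 and in the map of the Antennapedia complex.

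The strongest pb-GFP peak lay at the promoter of Ugalt, a UDP-galactose transporter gene, and was ranked 1 in each of the 3 libraries. It spanned positions 2703673 to 2704086 of chromosome X (dm6), with its summit at 2703891, 39 bp upstream of the nearest start site of Ugalt, and eIF2Bbeta also starts within 1000 bp. The reference sequence from 2703871 to 2703911 is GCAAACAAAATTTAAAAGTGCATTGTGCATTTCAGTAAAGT, and none of the 11 fixed motifs occurred within 100 bp of this summit. The next strongest lay 1376 bp upstream of cbt, which encodes a zinc finger transcription factor, at 2L 480881 to 481307 in an intron of the overlapping gene ush. The one after it lay at a start site of px, a wing vein gene, at 2R 22514103 to 22514509. Their mean ranks over the libraries were 2.67 ± 1.15 (SD, n = 3) for cbt and 3.0 for px, which was ranked 3 in every library. The remaining genes nearest to the 15 strongest peaks found in all 3 lists were CG14100, CG11050, Lk6, PNPase, Art3, CG1888, mRpL41, Chro, tara, CG4004, CG9663 and ph-p. They include a protein kinase gene (Lk6), an arginine methyltransferase gene (Art3), the chromodomain gene Chro and the Polycomb group gene ph-p. The ph-p peak, at X 2137168 to 2137555, had a mean rank of 13.7 ± 4.16 (SD, n = 3).

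Most thresholded peaks were present in each library's list, as their selection favours. The thresholded list was called on the alignments of these same libraries together. It holds the 2740 strongest peaks of that combined list, cut on the irreproducible discovery rate, so its peaks were not kept individually for agreement. A summit of the replicate list lay within 100 bp of 94.3% of the thresholded summits in replicate 1, 97.7% in replicate 2 and 95.4% in replicate 3, a mean of 95.8% ± 1.70 (SD, n = 3). Circular shifts of the peaks along their chromosome arms gave 4.53%, and because of that selection the difference is no independent test of repeatability. In all 3 lists stood 2421 peaks (88.4%), among them those of Ugalt, cbt, px and ph-p named above. The ranked lists of the libraries, made without that selection, were compared in pairs. Among the 2740 highest ranked peaks of each library, replicates 1 and 2 shared 59.9%, replicates 1 and 3 shared 53.1% and replicates 2 and 3 shared 59.9%, a mean of 57.7% ± 3.91 (SD over 3 pairs) against 0.41% by chance (permutation p = 0.002 for each pair, the smallest that 1000 shifts can give). These shifts do not keep the closeness of peaks to start sites. The comparison therefore does not separate agreement on single sites from a preference for promoters that the lists have in common. Of the thresholded peaks, 1280 (46.7%) were among the top peaks of all 3 libraries, and 59 (2.15%) were among those of none. Across the 2469 to 2552 thresholded peaks matched in a pair of libraries, which are not independent replicates and were selected as above, Spearman's rho of the signal values was 0.645, 0.580 and 0.631 and Pearson's r of the log2 signal was 0.731, 0.674 and 0.710, in the same order of pairs.

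Promoters of protein-coding genes held most pb-GFP peaks. Of the 2740 summits, 1733 (63.2%) lay within 1000 bp of a transcription start site, against 20.3% after circular shifts, a ratio of 3.11 (permutation p = 0.002, the smallest possible). The share among the top peaks of the libraries was 62.1% ± 1.41 (SD, n = 3), and 1127 summits (41.1%) lay within 200 bp of a start site. Every other class held a smaller share of all summits than chance, in part because shares sum to the whole and promoters took more. Introns held 24.3% against 36.4%, intergenic sequence 11.0% against 28.3%, 3′ UTRs 0.803% against 3.85% and coding exons 0.474% against 10.7% (adjusted permutation p = 0.0024 each), and 5′ UTRs beyond the promoter window held 0.182% against 0.462% (adjusted permutation p = 0.040). The 5′ UTR share rests on 5 peaks, and it was no longer apart from chance among the stronger 1370 peaks (adjusted permutation p = 0.256) or when any library was left out (from 0.128 without replicate 1 to 0.282 without replicate 3). With a promoter window of 500 bp it was 0.803% against 0.796% (adjusted permutation p = 1.0). Among the 1007 summits outside promoters, a comparison added after the data were examined, introns held more than chance, 66.1% against 45.7% (adjusted permutation p = 0.0033). There coding exons (1.29% against 13.5%), 3′ UTRs (2.18% against 4.83%) and intergenic sequence (29.9% against 35.4%) still held less (adjusted permutation p up to 0.0050), and 5′ UTRs did not pass (0.497% against 0.590%, 0.607). Coding exons held 4.49% of the top peaks in replicate 1, against 0.438% in replicate 2 and 0.547% in replicate 3. Along the combined list the promoter share fell from 65.4% (exact 95% interval 61 to 69.6) at ranks 1 to 500 to 56.9% (54.9 to 59.0) at ranks 2741 to 5000 and 29.2% (28.3 to 30.1) at ranks 20001 to 30000.

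**Figure D1:**
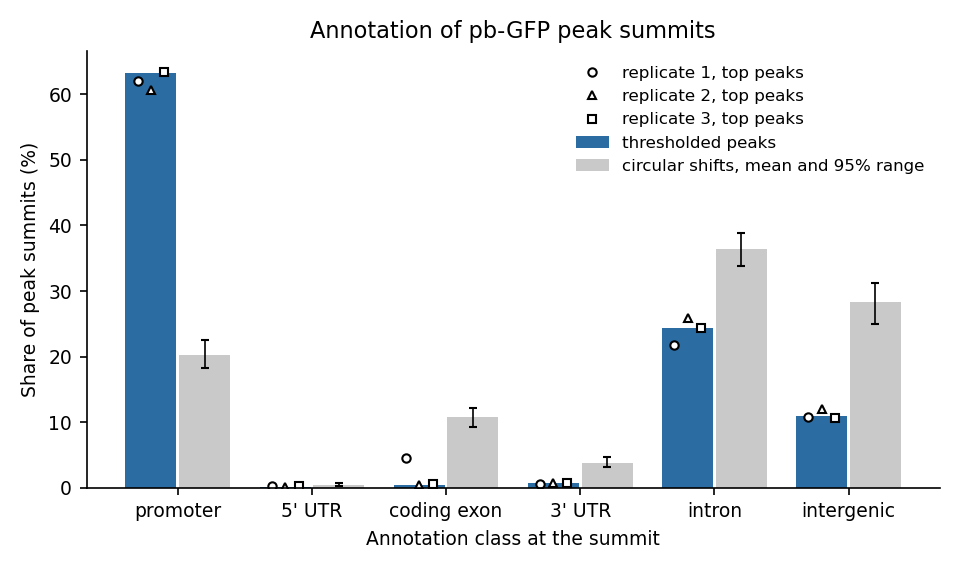
Share of peak summits (%, vertical axis) in each annotation class (horizontal axis). Blue bars are the 2740 thresholded peaks, grey bars the mean of 1000 circular shifts with their 95% range, and open symbols the 2740 top peaks of each library; promoters held 63.2% of summits against 20.3% by chance, and replicate 1 stood apart in coding exons at 4.49%.

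Chromosome 4 carried few peaks, and few of the background regions too. It had 8 thresholded peaks, or 6.45 per Mb, 0.310 times its share of the covered length (exact binomial test, adjusted p = 5.7e-04). The density was 21.1 per Mb on 2L, 22.1 on 2R, 19.2 on 3L, 20.7 on 3R and 21.8 on X, and none of these arms passed the threshold (adjusted p from 0.119 on 3L to 0.929 on 3R, exact binomial tests). The scarcity was not particular to the thresholded peaks, since only 44 of the 30000 peaks and background regions of the combined list, and 26, 128 and 181 of those of replicates 1 to 3, lay on chromosome 4, which makes up 0.941% of the covered length. The X chromosome of these mixed-sex embryos held 1.05 times its share of the length, and 0.979 times on the dm3 list (exact binomial test, adjusted p = 0.609). The chromosome 4 count was 3 among the top peaks of replicate 1 and 11 in each of replicates 2 and 3, and the call was lost among the stronger 1370 peaks (4.84 per Mb, adjusted p = 0.154) and without replicate 1 (5.65 per Mb, adjusted p = 0.0565, exact binomial tests). Without replicates 2 and 3 in turn the ratio was 0.219 and 0.196. Leaving out a library keeps only the 1454 to 1624 thresholded peaks among the top peaks of both others. In these smaller sets 3L fell below its share without any of the libraries (ratio 0.856 to 0.877, adjusted p from 0.0117 to 0.0319), and X rose above it without replicate 1 (1.14, 0.0319) and replicate 2 (1.14, 0.0376; exact binomial tests). On the dm3 list 2R stood above its share (ratio 1.12, exact binomial test, adjusted p = 0.00911). The binomial tests take each peak as an independent draw, while peaks cluster at some genes, so their p may be too small.

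The Hox genes themselves carried pb-GFP peaks, most of them in the weaker part of the thresholded list. Their 11 peaks had a median rank of 2085 of 2740 (best rank 997), and only 2 lay within 1000 bp of a start site. A thresholded peak had its nearest start site in 7 of the 8 Hox genes, against 2.24 in random peak sets that keep the distances to start sites (ratio 3.13, adjusted permutation p = 0.0092). pb had 1 peak, at 3R 6723950 to 6724359 (dm6), with its summit at 6724155 in an intron 17908 bp from the start site and ranks of 1420, 2338 and 4345 in replicates 1 to 3. The reference sequence at 6724135 to 6724175 is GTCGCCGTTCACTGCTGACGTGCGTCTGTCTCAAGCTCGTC. Antp, the Hox gene of the second thoracic segment, had 3 peaks, the strongest in an intron at 3R 6914378 to 6914787 with a mean rank of 1250.3 ± 515 (SD, n = 3). lab had 1 peak 87 bp upstream of its start site, Dfd had 2, and Scr had none. In the bithorax complex, abd-A had 1 peak (best rank 1249), Abd-B had 2 (best rank 1324) and Ubx had 1 (rank 2577), which was not matched within 100 bp in replicate 2. Of the Hox cofactor genes, hth had 2 peaks, the stronger in an intron at 3R 10564266 to 10564675, and exd had none. Among the top peaks of each library, 6, 5 and 6 Hox genes were nearest to a peak in replicates 1 to 3. The Hox count was not apart from circular shifts, which gave 3.64 members (adjusted permutation p = 0.276). These shifts do not keep the distances of peaks to start sites. The Hox count was also not apart from chance without replicate 1 (2 members, adjusted permutation p = 1.0) or without replicate 3 (4 members, 0.194). It also failed with peaks assigned by gene body (6 members, 0.0919), with start sites within 5000 bp only (4 members, 0.433) and among the stronger 1370 peaks (3 members, 0.429; adjusted permutation p).

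**Figure D2:**
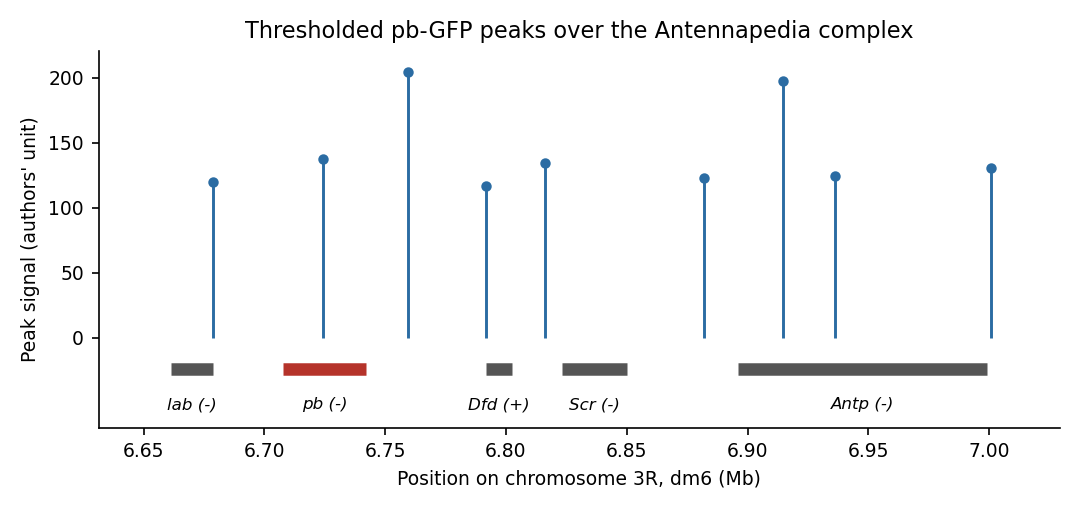
Thresholded peaks on chromosome 3R, dm6, over the Antennapedia complex (horizontal axis, position in Mb). Each of the 9 stems is a peak with its signal value in the authors' unit (vertical axis), and bars below are the gene bodies with their strand, pb in red; the signal runs from 116 at the Dfd promoter to 204 at the bcd promoter.

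The locus of the tagged gene did not stand out. The pb gene with 50 kb to either side (3R 6657800 to 6792063) held 4 thresholded peaks, at 0.298 per 10 kb, more than in 65.5% of 1000 random windows of 3R (permutation p = 0.691). These were the peaks at lab, pb, Dfd and the promoter of bcd, a gene picked out after its values were seen. Without replicate 1 or 2, and among the stronger 1370 peaks, the density was 0.0745 per 10 kb (permutation p = 1.0), and without replicate 3 it was 0.149 (permutation p = 0.943). In the full lists the same window held 56 peaks in replicate 1, 57 in replicate 2 and 35 in replicate 3, a mean of 49.3 ± 12.4 (SD, n = 3), with permutation p of 0.118, 0.106 and 0.863.

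Cytoplasmic ribosomal protein genes were often found at pb-GFP peaks. Of the 92 genes of the list, 62 were nearest to a peak, against 16.3 in random peak sets (ratio 3.8, adjusted permutation p = 0.0092). The libraries gave 63, 56 and 61 (SD 3.61, n = 3). Their 66 peaks lay almost at the start site, 62 of them within 200 bp and with a median distance of 21 bp. RpS27 (rank 42), RpL41 (rank 79), RpL23A (rank 86) and RpL14 (rank 89) had the strongest. The list had been fixed as a contrast to the developmental lists. It was fixed by symbol and took in RpL7-like, RpL22-like, RpL24-like, RpLP0-like and RpS28-like, none of which had a peak. Other contrast lists had fewer members at peaks than chance: 3 of 119 odorant and gustatory receptor genes (Gr93d, Gr93a and Gr89a; ratio 0.179) and 3 of the 85 genes of the cytochrome P450 list (Cyp4d21, Cyp6v1 and Cyp310a1; ratio 0.226), each with an adjusted permutation p of 0.0092. The P450 list was fixed by symbol and took in the cyclophilin genes Cyp1 and Cyp40, without which it had 3 of 83 (ratio 0.235, adjusted permutation p = 0.0092). Proteasome subunit genes had 3 of 48 (ratio 0.402, adjusted permutation p = 0.205). The ribosomal protein ratio was 8.33 against circular shifts, 2.63 with peaks assigned by gene body, 5.81 among the stronger 1370 peaks and 5.83 without replicate 2, and passed in each (adjusted permutation p from 0.0115 to 0.0230). The receptor call was lost without replicate 3 (3 members, ratio 0.294, adjusted permutation p = 0.0804). The P450 call was lost among the stronger 1370 peaks (0.138) and without any of the libraries (adjusted permutation p from 0.0996 without replicate 3 to 0.168 without replicate 1, where the ratio was 0.375).

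Polycomb and trithorax group genes, which maintain Hox expression states, were the developmental list with the firmest count. A peak was nearest to 11 of 20 members, against 4.17 by chance (ratio 2.63, adjusted permutation p = 0.0092), and each library gave 10. Besides ph-p, with 4 peaks, these included osa (rank 36, in an intron), Trl, which encodes GAGA factor (ranks 64 and 201), and Psc (4 peaks, best rank 701). Among the stronger 1370 peaks 7 members had a peak (adjusted permutation p = 0.103). Against circular shifts the ratio was 4.35 (adjusted permutation p = 0.0153). Those shifts placed 20.3% of summits in promoters, against 63.2% observed, so they do not keep the concentration of peaks there. They gave 2.53 Polycomb and trithorax group and 7.4 ribosomal protein genes, against 4.17 and 16.3 in random peak sets. For Hox genes the order was the other way, 3.64 against 2.24.

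Segment polarity genes had 7 of 13 members at peaks (ratio 3.14, adjusted permutation p = 0.038), among them ptc, the Hedgehog receptor gene, with 3 peaks (best rank 1105), nkd with 2, mid (rank 584) and en with a promoter peak (rank 1724). Salivary gland and tracheal regulators had 6 of 10 (ratio 3.19, adjusted permutation p = 0.039), with promoter peaks at fkh (rank 140), eyg (rank 594) and the FGF gene bnl (rank 774), and an upstream peak at CrebA (rank 709). The top peaks of replicates 1 to 3 gave 6, 4 and 4 segment polarity genes and 6, 5 and 6 salivary and tracheal genes. Neither list stood apart from circular shifts (adjusted permutation p = 0.302 and 0.276). Both calls were also lost without replicate 1 (3 members, p = 0.509; 5 members, p = 0.0735) and without replicate 3 (3 members, p = 0.541; 4 members, p = 0.171), and the segment polarity call without replicate 2 (3 members, p = 0.477; all adjusted permutation p). Without replicate 2 the salivary and tracheal ratio was 4.96. By gene body the adjusted permutation p was 0.993 for segment polarity and 0.514 for salivary and tracheal genes. It was 0.262 and 0.0996 with start sites within 5000 bp, and 0.429 and 0.112 among the stronger 1370 peaks.

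The other developmental lists did not pass the test. The EGF receptor pathway had 6 of 10 members (ratio 2.71, adjusted permutation p = 0.063), and passed without replicate 2 (ratio 4.13, p = 0.0230) or replicate 3 (ratio 4.47, p = 0.0153; adjusted permutation p). The top peaks of each library gave 7 members, and against circular shifts the ratio was 1.71 (adjusted permutation p = 0.492). BMP and Wnt ligands and receptors had 7 of 15 (p = 0.082) and axon guidance and cell adhesion genes 7 of 16 (p = 0.124; adjusted permutation p throughout). Counts were 2 of 4 other Antennapedia complex regulators, 1 of 7 Hox cofactors and TALE homeobox genes, 3 of 13 gap and head patterning genes, 4 of 10 pair rule genes, 7 of 20 appendage patterning genes and 4 of 23 neuroblast and proneural regulators. They were 4 of 10 neuronal identity regulators, 3 of 6 glial regulators, 5 of 17 mesoderm and muscle regulators, 3 of 8 GATA factors and blood cell regulators, 2 of 10 Notch pathway genes and targets and 2 of 4 cell death inducers, with adjusted permutation p from 0.300 to 1.0. By Fisher's exact test over all protein-coding genes, which takes no account of distances, the EGF receptor (adjusted p = 0.0041), BMP and Wnt (0.0082), axon guidance (0.0115) and appendage (0.0414) lists also passed. In all, 5 of the 23 lists had more and 2 had fewer members at peaks than chance, and with circular shifts 2 had more and 2 fewer. Without replicate 1 there were 2 lists with more members and 1 with fewer, without replicate 2 there were 5 and 1, and without replicate 3 there were 3 and 0.

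**Figure D3:**
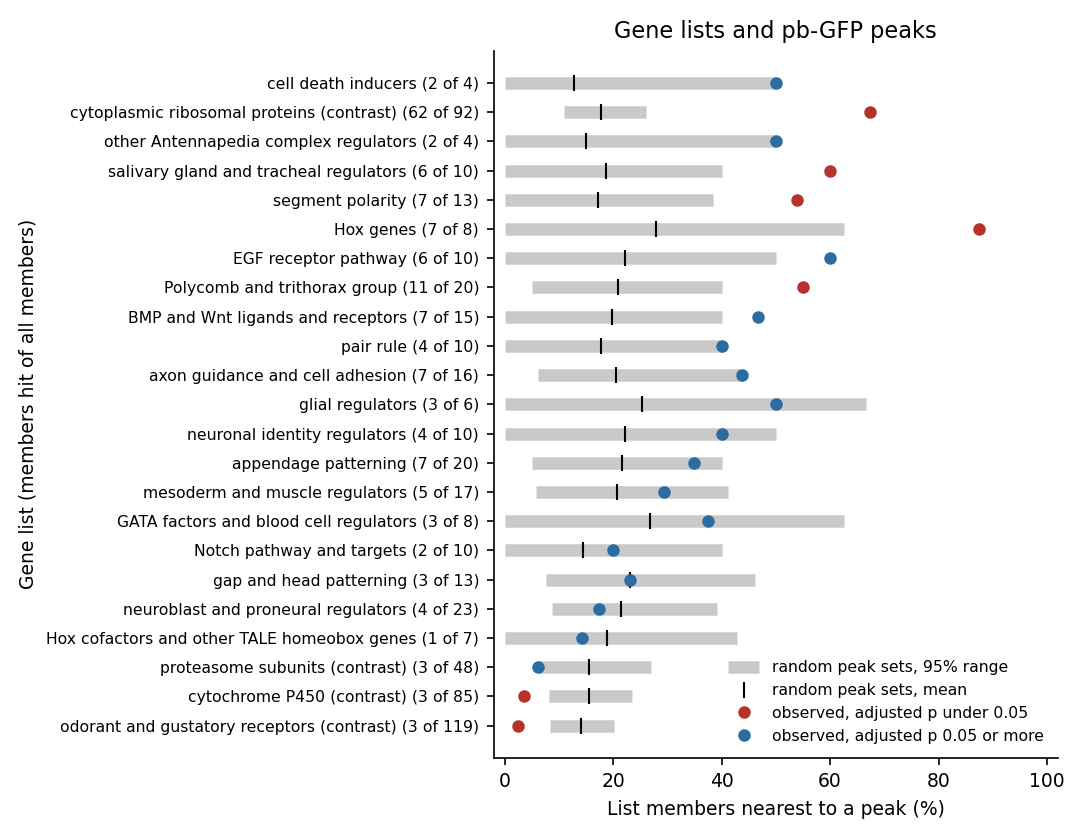
Share of the members of each fixed gene list that were nearest to a thresholded peak (%, horizontal axis), with the lists on the vertical axis. Points are the observed shares, red where the adjusted permutation p was under 0.05, and grey bars and ticks are the 95% range and mean of 1000 random peak sets; ribosomal protein genes reached 67.4% and odorant and gustatory receptor genes 2.52%.

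Some genes carried many peaks. The thresholded peaks had their nearest start site in 2052 of 13945 protein-coding genes (14.7%), 1621 of them with 1 peak and 25 with 5 or more. tara, a transcriptional co-regulator gene, had 11, shn, a zinc finger gene of BMP signalling, had 10, and the ecdysone-induced nuclear receptor gene Eip75B and the forkhead gene CHES-1-like had 9 each. sbb, named after its count was seen, and Raf, the kinase gene of the MAP kinase cascade, had 8 each. Of the Raf peaks, 7 lay between 2296121 and 2306766 on X. The strongest tara peak was 3148 bp upstream of its nearest start site at 3R 16222322 to 16222658, with a mean rank of 11.7 ± 5.13 (SD, n = 3). The assignment to genes is uncertain for 656 peaks (23.9%), which had start sites of more than 1 gene within 1000 bp. It is also uncertain for peaks far from any start site, among them 184 (6.72%) at more than 10000 bp.

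The DNA replication-related element (DRE), TATCGATA, was the fixed motif most concentrated at summits, while homeodomain sites were not. The DRE lay within 100 bp of 121 summits (4.42%) against 0.620% of flanking windows, a ratio of 7.12 (sign-flip permutation test, adjusted p = 5.5e-05), and the ratio over the libraries was 5.53 ± 0.743 (SD, n = 3). The ratio was lower among the stronger 1370 peaks (4.40) and with windows of 250 bp (4.04), and the DRE did not pass at the 200 strongest peaks (3.5% against 1.5%, ratio 2.33, adjusted permutation p = 0.734). At the 1733 promoter peaks the shares were 6.81% and 0.664%, and at the 1007 other peaks 0.298% and 0.546%. The GAGA factor site GAGAGAG lay at 7.15% of summits against 4.60% of flanks (ratio 1.56, adjusted permutation p = 5.5e-05). Its ratio was 1.86 at promoter peaks and 1.12 at the others, where it did not pass (adjusted permutation p = 0.828), nor did it with windows of 50 bp (ratio 1.12, 0.875) or among the stronger 1370 peaks (ratio 1.42, 0.0578). The homeodomain core TAATTA lay at 12.3% of summits and 11.8% of flanks (adjusted permutation p = 0.675), and TAATGA at 11.0% and 11.5% (0.675). The Exd-Hox pattern TGATNNAT lay at 10.9% and 12.4% (adjusted permutation p = 0.141). TGATGGAT, the Exd-Hox site of the labial and proboscipedia class, was found at 8 summits, 0.292% against 0.766% of flanks (ratio 0.381, adjusted permutation p = 0.013), and was not apart from flanks without replicate 1 (adjusted permutation p = 0.143) or replicate 2 (0.0816), nor among the stronger 1370 peaks (0.0578), while it was without replicate 3 (ratio 0.200, 0.0189). Windows of 50 bp (0.242) and 250 bp (0.103) also ended the call. TGATNNAT passed as depleted with windows of 250 bp (ratio 0.880, adjusted permutation p = 0.0019) and flanks at 2000 bp (ratio 0.859, 0.0393).

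Zelda, E-box, GATA and CA repeat sites did not pass the test over all thresholded peaks either. Their ratios were 0.806 for CAGGTAG, 1.11 for CAGCTG, 0.873 for CACGTG, 0.947 for AGATAAG and 1.03 for CACACACA, with adjusted permutation p from 0.282 to 0.761. With windows of 250 bp CAGCTG (ratio 1.18, adjusted permutation p = 1.6e-04) and CACACACA (ratio 1.30, 3.7e-05) passed, and CACACACA also with flanks at 2000 bp (ratio 1.51, 5.1e-04). At the promoter peaks alone CAGCTG passed, at 13.6% against 11.1% (ratio 1.23, adjusted permutation p = 0.034), while at the other peaks its ratio was 0.823 (adjusted permutation p = 0.490). At the 200 strongest peaks CACACACA lay at 0.50% of summits against 7.5% of flanks (adjusted permutation p = 1.1e-04). The 5.5e-05 above belongs to a raw p of 1e-05, the smallest that 100000 sign flips can give. Summits were poorer in GC than flanks, at 40.5% against 43.0% over all thresholded peaks and 38.9% against 43.5% over the 200 strongest.

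**Figure D4:**
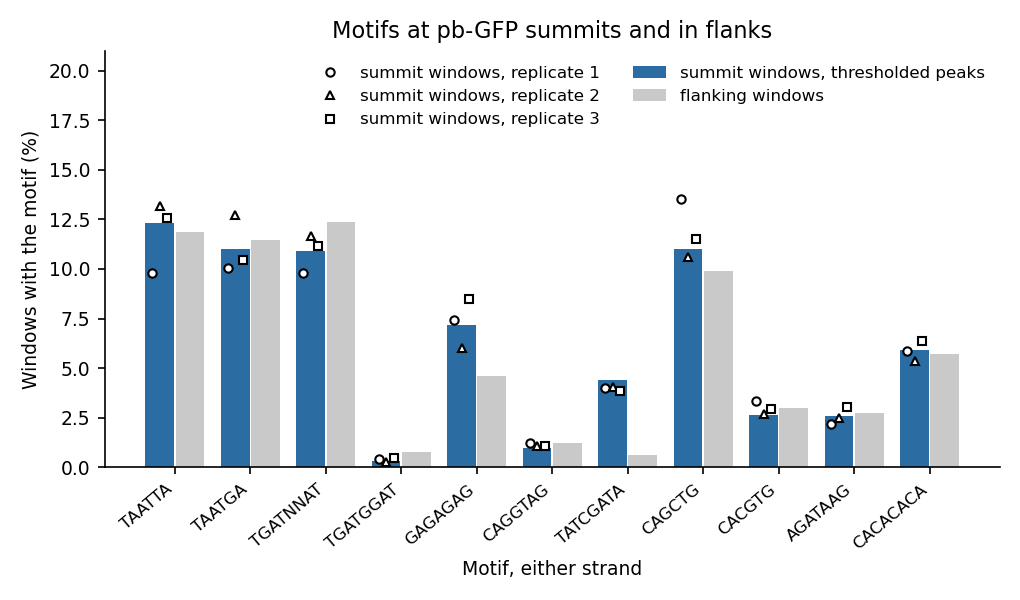
Share of windows holding each fixed motif (%, vertical axis), by motif on either strand (horizontal axis). Blue bars are windows of 100 bp to either side of the 2740 thresholded summits, grey bars windows centred 1000 bp to either side, and open symbols the summit windows of the 2740 top peaks of each library; TATCGATA stood at 4.42% against 0.620%, and TAATTA at 12.3% against 11.8%.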

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

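Tests without a replicate of annotation, arms and motifs, unmasked bases as the arm length, summits outside promoters and the P450 list without cyclophilin genes were chosen only after the results were seen. Of 418 alternatives, 303 were counted as unchanged, among them each one for replicate recovery, overlap of top peaks and promoter share (53.4 to 73.2%). For tests this means the same direction and side of the threshold. For counts and the rank correlation, which have no test, it means a similar value. Recovery and overlap without a replicate were entered as unchanged without that rule, and each stayed above chance (permutation p = 0.002). Where a value below changed, the cause was not tested, except that smaller peak sets lower densities and counts by construction. Gene list and motif values are ratios to chance or flanks. With the 1370 strongest peaks, the 5′ UTR share was 0.219%, chromosome 4 4.84 per Mb and the pb locus 0.0745 per 10 kb; Hox 2.51, Polycomb 3.09, segment polarity 2.39, salivary and tracheal 4.16 and P450 0.293 no longer passed; Hox cofactors 1.45, gap and head 1.75, GATA and blood cell 0.845 and Notch 0 turned; 1 list had more and 1 fewer members than chance; TGATGGAT 0.286 and GAGA 1.42 no longer passed and CA repeats 0.852 turned. With promoters of 500 bp the 5′ UTR share was 0.803%. Outside promoters introns turned to above chance (66.1%), as shares there no longer fall with the promoter rise, and 5′ UTRs no longer passed (0.497%). On dm3, where densities rest on other arm extents, 2L (22.0 per Mb, ratio 0.948) and X (22.7, 0.979) turned to below their share of the length, 3R (24.0, 1.04) turned to above it, and 2R (26.0, 1.12) passed. By gene body, Hox 2.49, segment polarity 1.42 and salivary and tracheal 1.99 no longer passed, pair rule 0.750 and neuronal identity 0.772 turned, and 2 lists had more members. Within 5000 bp, Hox 1.94, segment polarity 2.29 and salivary and tracheal 2.92 no longer passed, leaving 2 lists. With circular shifts, Hox 1.92, segment polarity 1.84 and salivary and tracheal 2.17 no longer passed, appendage 0.886 turned, and 2 lists had more members. By Fisher's exact test, gap and head 1.57 and neuroblast 1.18 turned, appendage 2.38, EGF receptor 4.08, BMP and Wnt 3.17 and axon guidance 2.97 passed, and 9 lists had more members. With windows of 50 bp, TAATTA 0.997 and CA repeats 0.775 turned, and TGATGGAT 0.375 and GAGA 1.12 no longer passed. With 250 bp, TGATNNAT 0.880, CAGCTG 1.18 and CA repeats 1.30 passed, TGATGGAT 0.682 did not, and CACGTG 1.13 turned. With flanks at 2000 bp, TGATNNAT 0.859 and CA repeats 1.51 passed and GATA 1.07 turned. Away from promoters, TAATTA 0.888, Zelda 1.23, DRE 0.545, CAGCTG 0.823, GATA 1.07 and CA repeats 0.992 turned, and TGATGGAT 0.421 and GAGA 1.12 no longer passed. Leaving out each replicate in turn gave a rank correlation of 0.580 to 0.645, a 5′ UTR share of 0.185 to 0.246%, densities per Mb of 9.45 to 10.8 on 3L, 2.42 to 5.65 on 4, 12.5 to 14.0 on X and 10.9 to 12.7 on 3R, and 0.0745 to 0.149 per 10 kb at the pb locus. Ratios were 1.43 to 3.91 for Hox, 1.22 to 1.36 for Hox cofactors, 1.03 to 1.52 for gap and head, 0.940 to 2.00 for pair rule, 2.02 to 2.34 for segment polarity, 3.26 to 4.96 for salivary and tracheal, 0.705 to 0.831 for GATA and blood cell, 3.58 to 4.47 for EGF receptor, 0.197 to 0.294 for odorant and gustatory receptor and 0.251 to 0.375 for P450 genes, with 2 to 5 lists having more and 0 to 1 fewer members. They were 0.200 to 0.400 for TGATGGAT, 0.944 to 0.977 for CA repeats, 0.933 to 1.01 for CACGTG and 0.913 to 1.04 for TAATGA. Read depth is unknown, so what it limits was not assessed.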

Other observations

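The gene families and words of the first paragraphs, the TAATTA interval, and the use of circular shifts beside length-matched lists for Hox, salivary and tracheal genes were tests chosen only after results were seen.

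Eip75B and Hr4, nuclear receptor genes of the ecdysone response, carried 9 and 7 thresholded peaks, and EcR (rank 452) and Hr3 (rank 482) carried 1 each. Of 21 nuclear hormone receptor genes 10 were nearest to a peak, a ratio of 1.72 to random peak sets (adjusted permutation p = 0.188 over 6 families), with 10, 9 and 10 in replicates 1 to 3. None of the 6 families passed. Mitochondrial ribosomal protein genes had 7 of 73 (0.578) and translation initiation factor genes 10 of 44 (0.578). CPR cuticle protein genes had 3 of 70 (0.108), odorant binding protein genes 3 of 51 (0.188) and vacuolar ATPase genes 5 of 33 (1.0; all adjusted permutation p). Promoter peaks had start sites of more than 1 gene as often as random promoter placements, 37.9% against 38.3% (permutation p = 0.757).

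Words of 8 bases were picked on the odd-ranked thresholded peaks and tested on the 1370 even-ranked ones, where 12 of 12 were more frequent at summits than in flanks (adjusted sign-flip permutation p up to 0.0037). Of these, 4 held TATCG, the core of the DRE, and 6 held CACTG on either strand. CACTGTGC lay at 4.89% of summits against 0.876% of flanks (ratio 5.58), with 36 of its 67 peaks at promoters. CACAGTGG lay at 4.74% against 0.985%. CAACACTG was found at promoters in 49 of 50 peaks, and TATCGATA in 58 of 59. The words, like the GAGA factor site, were compared with flanks only and not with start sites of genes without a peak. What their ratios owe to promoter position was therefore not tested. Some of the words overlap one another, so they are not separate findings.

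The DRE stood out at promoter peaks of pb-GFP, in 6.81% of summit windows. Base composition is argued against, since the highest gain over flanks among 73 shuffles of its letters was 2.74 points against 6.15 for the element. Promoters in general are argued against as the whole cause, since windows at the same offsets from other start sites held it in 3.89% (95% range 3.06 to 4.85, permutation p = 0.002, the smallest possible). Those sites belonged to 11893 genes that were not nearest to any thresholded summit. Some of them may still share a promoter with a peak, as 656 promoter peaks had start sites of more than 1 gene within 1000 bp. The frequency of homeodomain sites decides nothing about the DRE, since neither outcome could account for or exclude TATCGATA at promoters, and the ratios of summits to flanks over all peaks were 1.04 for TAATTA (95% bootstrap interval 0.918 to 1.18), 0.960 for TAATGA, 0.881 for TGATNNAT and 0.381 for TGATGGAT. Binding by the tagged protein, or by a protein partner that may bind the DRE, stays open. Recovery that does not depend on pb-GFP was not tested and stays open as well. The other start sites were matched on arm and offset only, so other properties that set promoters with peaks apart stay open too.

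Developmental lists could pass because long stretches of sequence lie nearest to their genes. Random lists matched on that length gave 3.32 members for Polycomb and trithorax genes against 11, and 10.9 for ribosomal protein genes against 62 (permutation p = 0.002 each, the smallest possible), which argues against length as the cause there. For segment polarity genes they gave 3.53 against 7 (permutation p = 0.0639), so length stays a candidate explanation. For salivary and tracheal genes they gave 2.56 against 6, which met the bound set beforehand against length only without adjustment (permutation p = 0.046, adjusted 0.176 over the 23 lists), and circular shifts gave 2.76 (permutation p = 0.0659), so the evidence against length is weak. For Hox genes they gave 2.90 against 7 (permutation p = 0.0040, adjusted 0.0230), which met that bound too, but it was set wrongly for them, as such draws take members as independent while all 7 Hox genes with a peak have another within 200 kb, and circular shifts, which keep neighbours together, gave 3.64 (permutation p = 0.0719), so length cannot be told apart there.

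Replicate 1 held more coding exon peaks among its top peaks (4.49%) and fewer chromosome 4 peaks in its full list (26, against 128 and 181). A preference for GC-rich fragments may contribute to the coding exon peaks, since intron and intergenic summits below the top peaks were 3.20 points richer in GC (47.1%, against 43.9% and 42.6%). Fewer enriched sites may also contribute, since among peaks at the largest −log10 q the coding exon share of replicate 1 was 0.584% (exact 95% interval 0.235 to 1.20), against 0.441% and 0.555%. For chromosome 4, GC content is argued against as the whole cause, since it predicted 112.6 peaks from replicate 3 and 98.4 from replicate 2 against the 26 found, whose upper Poisson bound was 38.1. No biological explanation was tested, and what lowered the chromosome 4 count stays open.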
